A study of Homo sapiens with 6 samples.

How the data were processed

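The data were 6 Affymetrix expression arrays of MCF10A, an immortalized, non-tumorigenic human mammary epithelial cell line. Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled cRNA was prepared from 6 µg of it. Per the series' design text, MCF10A cells were grown with breast fibroblasts for 3 weeks and then sorted before RNA extraction. Of the arrays, 3 came from cells grown with fibroblasts taken from breast tumours (CAF, cancer-associated fibroblasts) and 2 from cells grown with fibroblasts from normal breast tissue (NF). The remaining array came from MCF10A grown without fibroblasts (monoculture). The arrays of a coculture group differ in the fibroblast source, and the design text states that no replicates were run. A p-value here therefore rests on the spread between cultures with different fibroblast sources, as far as the deposited values hold it. An exact relation between the arrays, described below, makes a fit of 3 group means understate that spread. The spread of the monoculture was taken from the other groups. Replicate numbers only name the arrays within a group.

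The deposited values were 1 number per probe set and array, read as log2 expression. The scale was inferred from the values, which ran from 1.694 to 14.144 over all arrays. The summarisation, background correction and normalization that the authors used are not given in the sources used here. Array medians of the deposited log2 values lay between 5.102 and 5.2, and the correlation between arrays lay between 0.9742 and 0.9901 over all probe sets. No pair of arrays was a duplicate: the largest difference at any probe set was at least 2.461 log2 units in every pair. For these arrays the number of arrays limits the precision.

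The deposited table carried an exact linear relation. At each of the 54675 probe sets, CAF 3 equalled 0.5 times CAF 1 plus 0.5 times CAF 2 plus 0.75 times NF 1 minus 0.75 times NF 2, within 1.43e-06 log2 units. The table of 6 arrays thus had rank 5. This is the relation that remains after an effect of 2 sets of arrays, with CAF 1, CAF 2 and NF 1 in one set and CAF 3 and NF 2 in the other, is subtracted with the groups kept in the model. Among the 14 possible splits of the 5 cocultured arrays into 2 sets, 1 left a coefficient of 0 (under 1e-05) at every probe set. No label or header records such a step, and the set of the monoculture array cannot be read from the table. The relation means that the spread within groups holds 2 residual degrees of freedom and not the 3 that a fit of 3 group means counts.

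Of the probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and 11777 were not named. By Entrez identifier, 41043 of the 1-symbol probe sets matched the RefSeq gene table (GRCh38.p14), which was used for names only, and 0 symbols changed. No coordinates are given. The probe set with the highest mean over the 6 arrays stood for each of 19775 genes. Genes were tested if that mean was above the 40th percentile of all probe set means (4.639), which left 14390 genes. All columns of per-array values belonged to the 6 samples.

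Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend) on all 6 arrays, with 3 two-sided contrasts: CAF versus NF, CAF versus monoculture and NF versus monoculture. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, separately per contrast, and the threshold was 0.05. An exact permutation test of 3 arrays against 2 cannot give a p below 0.1, so none was used for single genes. A count without a p-value (the 2-fold rule) took genes at least 2-fold lower, or higher, in each CAF array than in each of the other 3 arrays. In total, 22 gene lists with 427 entries, of which 352 were tested, were compared with all other genes by camera with a preset inter-gene correlation of 0.01, and adjusted over the lists within a contrast. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera also used only the residual degrees of freedom, so a higher p there need not reflect correlation between genes. The estimate was below the preset for luminal markers (−0.042), matrix proteases (−0.064) and EGFR ligands and ERK response (−0.056). It was above the preset in other lists, such as keratinocyte differentiation (0.225). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

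Groups, tests, gene lists and the rule for named genes were fixed before the data were examined. For CAF versus NF, the rule named per direction the 12 genes with the largest log2 fold change among genes past the threshold whose arrays did not overlap between groups. For the contrasts with the monoculture it named 8. Where too few passed, it was filled with non-overlapping genes that had not passed. CST6 and AKT1, named in the series title, were always reported, as were up to 4 members of each list described. Genes without an official symbol, XIST and Y-linked genes were not named.

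After the linear relation had been seen, a fit with the 2 array sets as a term was added. Fold changes stay the same for CAF versus NF, and the residual degrees of freedom fall to 2. For the contrasts with the monoculture this fit was run with that array in either set. Both fits were tested on simulated data for the CAF versus NF comparison: 20 simulations of 14390 genes with 200 changed genes and an array-set effect (SD 0.5) added and then subtracted. The planned fit recovered 46.6% of changes of 1 log2 unit and 93.05% of changes of 2 log2 units. On average 32.45 of its 172.1 calls were false (18.86%). With the array sets as a term, 17.5% and 95.35% were recovered, and 6.9 of 119.8 calls were false (5.762%). These shares depend on the number and size of the simulated changes and do not carry over to the calls in the real data. Because the planned fit gave more false calls, counts from both fits are given side by side.

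Alternatives chosen before the data were examined were quantile normalization, equal array medians, no filter on dim probe sets or one at the 70th percentile, the variance prior without trend or robust, other rules for the probe set of a gene, a test per probe set, NF and monoculture as 1 group, the 5 cocultured arrays alone, folds of 1.5 and 3, and leaving out each array. Offsets before taking logs were not applicable to values already on a log scale.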

Results

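Expression was measured in MCF10A mammary epithelial cells after 3 weeks of coculture with breast fibroblasts, on 3 arrays with tumour-derived fibroblasts (CAF), 2 arrays with fibroblasts from normal breast tissue (NF) and 1 array without fibroblasts (monoculture). The design asks how the 2 kinds of fibroblast change gene expression in the epithelial cells, and the series title names CST6 as silenced and AKT1 as a mediator. Values are log2 expression as deposited. The monoculture array had no replicate.

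CST6, which encodes cystatin M, an inhibitor of lysosomal cysteine proteases, fell 5.29-fold in CAF coculture relative to NF coculture. The brighter of its probe sets, at the 73.1 percentile of probe set means, read 5.561 ± 0.287 (SD, n = 3) with CAF and 7.965 ± 0.19 (SD, n = 2) with NF, and the monoculture array lay between them at 6.603. The log2 fold change was −2.40 (SE 0.198, limma adjusted p = 0.03), and the adjusted p was 0.018 with the array sets as a term. Within the array sets the difference was −2.20 (CAF 1 and CAF 2 against NF 1) and −2.67 (CAF 3 against NF 2). Against the monoculture array neither coculture passed the test for CST6: the log2 fold change was −1.04 with CAF (adjusted p = 0.198) and 1.36 with NF (adjusted p = 0.142). A dimmer CST6 probe set, at the 33.6 percentile, differed by −0.26 between CAF and NF (adjusted p = 0.479 in a test of all probe sets). AKT1, the serine/threonine kinase of the title, read 7.283 ± 0.08 (SD, n = 3) with CAF and 7.424 ± 0.034 (SD, n = 2) with NF, against 7.553 in monoculture. Its log2 fold change of −0.14 (SE 0.111) did not pass (limma adjusted p = 0.593). This is the level of the AKT1 transcript, and kinase activity was not measured. Without CAF 1 or CAF 2 the adjusted p of CST6 was 0.0634 or 0.0809, and it was 0.143 with NF and monoculture as 1 group.

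**Figure D1:**
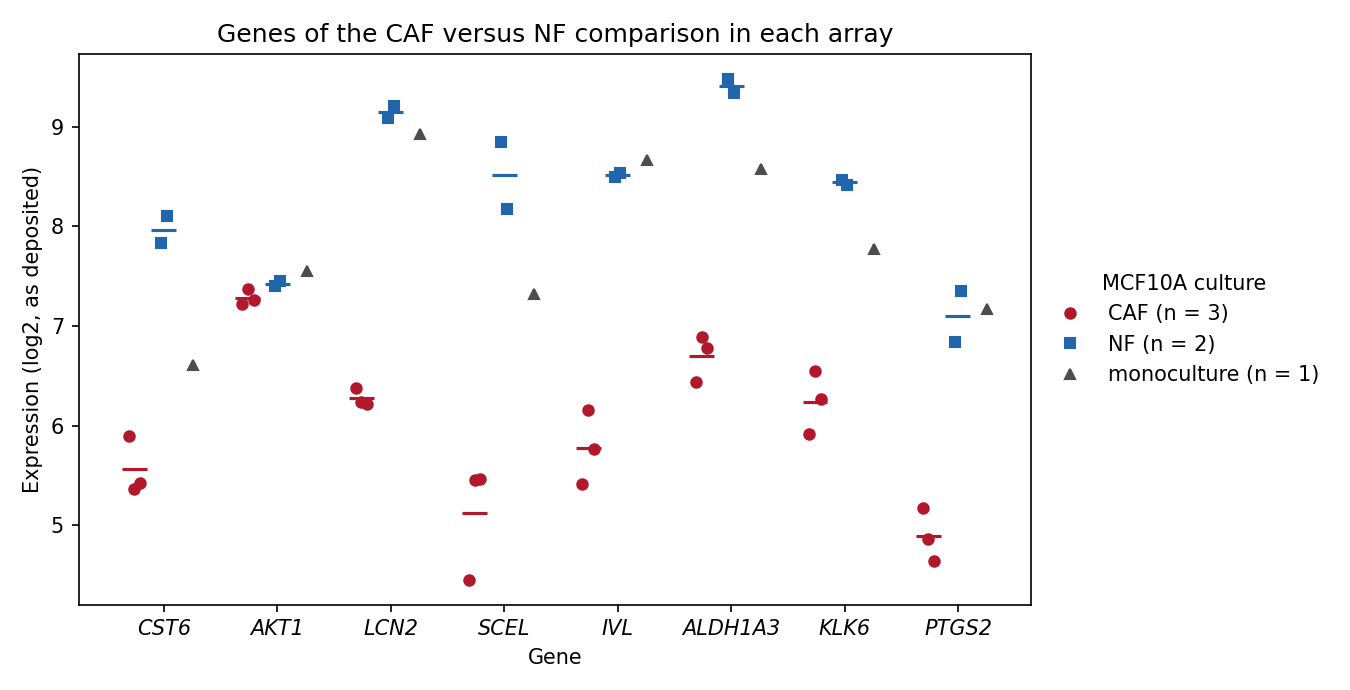
Log2 expression of 8 genes on the vertical axis in each array, with CAF arrays as circles (n = 3), NF arrays as squares (n = 2) and the monoculture array as a triangle, and group means as short lines. CST6 lies between 5.366 and 5.891 in the CAF arrays and at 7.831 and 8.1 in the NF arrays, while AKT1 lies between 7.218 and 7.553 in all 6.

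In CAF relative to NF coculture, all genes that passed the test were lower with CAF. They included secreted and surface products of epithelium and proteins of the differentiating squamous layer. LCN2, which encodes the siderophore-binding protein lipocalin-2, fell 7.31-fold, from 9.15 ± 0.082 (SD, n = 2) with NF to 6.279 ± 0.088 (SD, n = 3) with CAF. SCEL, a precursor of the cornified envelope, fell 10.5-fold, and IVL, the envelope protein involucrin, fell 6.67-fold. ALDH1A3, an enzyme that makes retinoic acid, fell 6.52-fold, and PTGS2, the inducible cyclooxygenase, fell 4.62-fold.

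Of 14390 genes, 50 passed in limma, 50 lower and 0 higher with CAF, and 45 of them differed at least 2-fold. Their median log2 fold change was −1.64. At an unadjusted p under 0.05 there were 2207 genes, 783 higher and 1424 lower, and without NF 2 there were 1048 higher and 1061 lower. Lower genes stayed in excess without CAF 1 (1097 against 454 higher), CAF 2 (1315 against 639) and CAF 3 (1047 against 741). In the simulation of the planned fit 12.6% of unchanged genes had an unadjusted p under 0.05. With the array sets as a term 44 genes passed, again 0 higher, and 35 of the 50 were among them. The count rested on single arrays: it was 1 without CAF 1, 0 without CAF 2 (limma, 1954 genes at an unadjusted p under 0.05), 136 without CAF 3 (14 higher) and 131 without NF 2 (14 higher). All 50 genes stayed lower with CAF whichever array was left out, but they had been chosen for low CAF values. With equal array medians 68 genes passed, 2 of them higher. The count was 22 after quantile normalization and 91 with the filter at the 70th percentile.

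The other genes named by the rule were AZGP1, the secreted zinc-alpha-2-glycoprotein, which fell 6.02-fold (log2 fold change −2.59, SE 0.246, limma adjusted p = 0.0327), and COXFA4L3, which fell 7.38-fold (adjusted p = 0.0413). The mean of AZGP1 with CAF, 4.207, lay below the level of the filter (4.639), so the size of its fall is uncertain. The kallikrein protease gene KLK6 had a log2 fold change of −2.20 (adjusted p = 0.0327). Falls of 4.63-fold for the zinc finger factor IKZF2, 4.62-fold for the adhesion receptor ADGRF1 and 4.01-fold for MACC1, a regulator of the receptor MET, also passed. For LCN2, SCEL, IVL, ALDH1A3 and PTGS2 the adjusted p was 0.00794, 0.047, 0.03, 0.0171 and 0.0389. All of these passed with the array sets as a term as well, with adjusted p from 0.00796 for LCN2 to 0.0263 for IKZF2. Quantile normalization ended the calls of SCEL, COXFA4L3 and IKZF2, and the mean of a gene's probe sets those of ALDH1A3, IKZF2 and PTGS2. With NF and monoculture as 1 group SCEL, COXFA4L3, AZGP1, IKZF2 and ADGRF1 did not pass (adjusted p from 0.0551 to 0.148), and SCEL and IKZF2 did not pass without the filter (0.0528) or with a robust prior (0.0519).

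In the other direction no gene passed, and the rule was filled with genes that were higher in every CAF array than in both NF arrays. AKR1B10, an aldo-keto reductase, read 8.725 ± 0.864 (SD, n = 3) with CAF and 6.362 ± 0.489 (SD, n = 2) with NF, a log2 difference of 2.36 (limma adjusted p = 0.139). SLC7A11, the cystine transporter, read 8.049 ± 0.709 (SD, n = 3) and 6.051 ± 1.057 (SD, n = 2) (limma adjusted p = 0.209). The matrix protein gene ECM2 differed by 2.01 (adjusted p = 0.14), and GPNMB, a transmembrane glycoprotein, by 1.58 (adjusted p = 0.12). For the remaining genes of the rule (NREP, GPX8, ABTB3, SFRP1, CLCA2, ABCC2 and GAS1) the differences lay between 1.53 and 1.66 with adjusted p from 0.167 to 0.366, and PAG1 read 5.911 ± 0.73 (SD, n = 3) with CAF and 4.412 ± 0.819 (SD, n = 2) with NF (limma adjusted p = 0.273). In SFRP1 the difference was 2.74 within the set of CAF 1, CAF 2 and NF 1 and 0.02 within the set of CAF 3 and NF 2.

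Genes of keratinocyte differentiation fell as a group in CAF relative to NF coculture. The median log2 fold change of 23 tested members was −1.22 (camera adjusted p = 4.82e-08; adjusted p = 0.283 with an estimated correlation). IVL and KLK6 passed as lower, 0 passed as higher and 21 did not pass. By sign, 19 members were negative and 4 positive. Adjusted over the list alone, 13 were lower and 0 higher. Among the members that did not pass, the keratin KRT4 read 6.536 ± 1.183 (SD, n = 3) with CAF and 10.201 ± 0.189 (SD, n = 2) with NF. The cornified envelope gene SPRR3 differed by −3.30 (limma adjusted p = 0.0621), and KRT13 by −3.07 (adjusted p = 0.102).

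Luminal epithelial markers also fell as a group, by a median of −0.32 over 13 members (camera adjusted p = 0.000401; adjusted p = 0.283 with an estimated correlation). None passed singly in limma, and 5 were lower adjusted over the list alone. CD24 differed by −1.68, the epithelial transcription factor ELF3 by −1.63, the keratin KRT7 by −1.53 and the tight junction gene CLDN7 by −1.36, with limma adjusted p of 0.218, 0.0621, 0.0512 and 0.0621. Basal epithelial markers did not shift: the median of 12 members was −0.04 (camera adjusted p = 0.668), with LAMB3 at −1.16 and KRT14 at 0.64, neither past the test. Fibroblast markers, listed to trace the coculture partner, had a median of 0.15 over 19 members (camera adjusted p = 0.279), with COL3A1 at 1.19 and FBLN1 at −1.27, and 1 member was lower adjusted over the list alone.

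FOXO target genes, PI3K-AKT pathway members and genes of EGFR ligands and the ERK response fell as groups with CAF relative to NF coculture. FOXO target genes, which are induced when AKT activity is low, had a median of −0.56 over 15 members (camera adjusted p = 8.67e-05; adjusted p = 0.283 with an estimated correlation). Of these, 0 passed singly and 9 were lower adjusted over the list alone, and the receptor ERBB3 differed by −1.37 (limma adjusted p = 0.0621). PI3K-AKT pathway members had a median of −0.16 over 18 members (camera adjusted p = 0.00949; adjusted p = 0.506 with an estimated correlation), 3 were lower adjusted over the list alone. That list's call ended without CAF 3 (adjusted p = 0.0738) or NF 2 (adjusted p = 0.278). The phosphatase INPP4B, a negative regulator of the pathway, fell 3.53-fold (log2 fold change −1.82, SE 0.168, limma adjusted p = 0.0327), and the other 17 did not pass. Its call ended after quantile normalization (adjusted p = 0.0615) and with NF and monoculture as 1 group (−1.30, adjusted p = 0.362). Genes of EGFR ligands and the ERK response fell by a median of −0.32 over 18 members (camera adjusted p = 0.0108; adjusted p = 0.283 with an estimated correlation), with 6 lower adjusted over the list alone. In that list DUSP5, an ERK phosphatase, fell 2.94-fold (limma adjusted p = 0.03, and 0.0547 after quantile normalization). Against the monoculture array the medians with CAF were −0.25 for FOXO targets, −0.19 for PI3K-AKT members and −0.24 for EGFR ligands and ERK response. None of these passed in the planned fit (camera adjusted p = 0.152, 0.219 and 0.0822). With NF the FOXO median lay 0.41 above that array (camera adjusted p = 0.0382).

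Genes of the TGF-beta response fell by a median of −0.42 over 18 members (camera adjusted p = 0.000401; adjusted p = 0.283 with an estimated correlation). None passed singly, 4 were lower adjusted over the list alone, and IGFBP3 and TGFBR2 differed by −1.43 and −0.91. Cell cycle and DNA replication genes fell by a median of −0.58 over 25 members (camera adjusted p = 0.00496; adjusted p = 0.506 with an estimated correlation). In that list 0 passed and 1 was lower adjusted over the list alone, and CDC20 and TOP2A differed by −1.37 and −1.32. Single arrays carried these differences, which were −0.75 and −0.67 without CAF 2, and −0.51 and −0.65 without NF 1, while CDC20 differed by −2.22 without NF 2. The median of the list was −0.29 without CAF 2, −0.32 without NF 1 and −0.90 without NF 2. The call ended with the filter at the 70th percentile (adjusted p = 0.0801) and with NF and monoculture as 1 group (adjusted p = 0.24). Matrix proteases and inhibitors fell by a median of −0.18 over 14 members (camera adjusted p = 0.0192; adjusted p = 0.283 with an estimated correlation), with 3 lower adjusted over the list alone and SPINT1 at −1.21. Handling stress genes fell by a median of −0.29 over 13 members (camera adjusted p = 0.00768; adjusted p = 0.651 with an estimated correlation), with 1 lower adjusted over the list alone.

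Several lists did not pass as groups in the planned fit. Cystatins and lysosomal cysteine proteases had a median of −0.14 over 18 members (camera adjusted p = 0.19); CST6 passed and CTSV, at −1.48, did not (limma adjusted p = 0.0718), and 2 were lower adjusted over the list alone. Genes reported methylated in breast cancer, a list that holds CST6, had a median of −0.17 over 17 members (camera adjusted p = 0.0871). CST6 and PTGS2 passed, and adjusted over the list alone 3 were lower and 1 higher. DNA methylation and Polycomb machinery had a median of −0.09 over 16 members (camera adjusted p = 0.544), with 0 past the threshold in either adjustment. Cytokines and NF-kB targets had a median of 0.29 over 15 members and a mean of −0.02 (camera adjusted p = 0.661), with LCN2 and PTGS2 lower and CXCL1 at 1.23. Over the settings tried CXCL1 ran from 0.65 to 1.81. Cholesterol synthesis genes were positive in 14 of 14 members with a median of 0.24 (camera adjusted p = 0.0879). Over the settings tried that median ran from −0.07 to 0.58. The stress response to unfolded protein and amino acid lack had a median of 0.19 (camera adjusted p = 0.0723), with PSAT1 at 1.61. Medians were −0.13 for interferon response, 0.09 for mesenchymal transition, 0.02 for hypoxia and glycolysis, 0.05 for immune and 0.04 for endothelial and adipocyte markers, and their camera adjusted p lay between 0.0624 and 0.668. No member of these 5 lists passed singly, and adjusted over the list alone 3 interferon and 1 mesenchymal genes were lower. Camera with the array sets as a term passed 4 of the lists, lower for interferon response (adjusted p = 0.0425) and for genes reported methylated (0.0376), and higher for cholesterol synthesis (0.0247) and for the stress response to unfolded protein (0.0178). With an estimated correlation in the planned fit their adjusted p lay between 0.385 and 0.737.

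**Figure D2:**
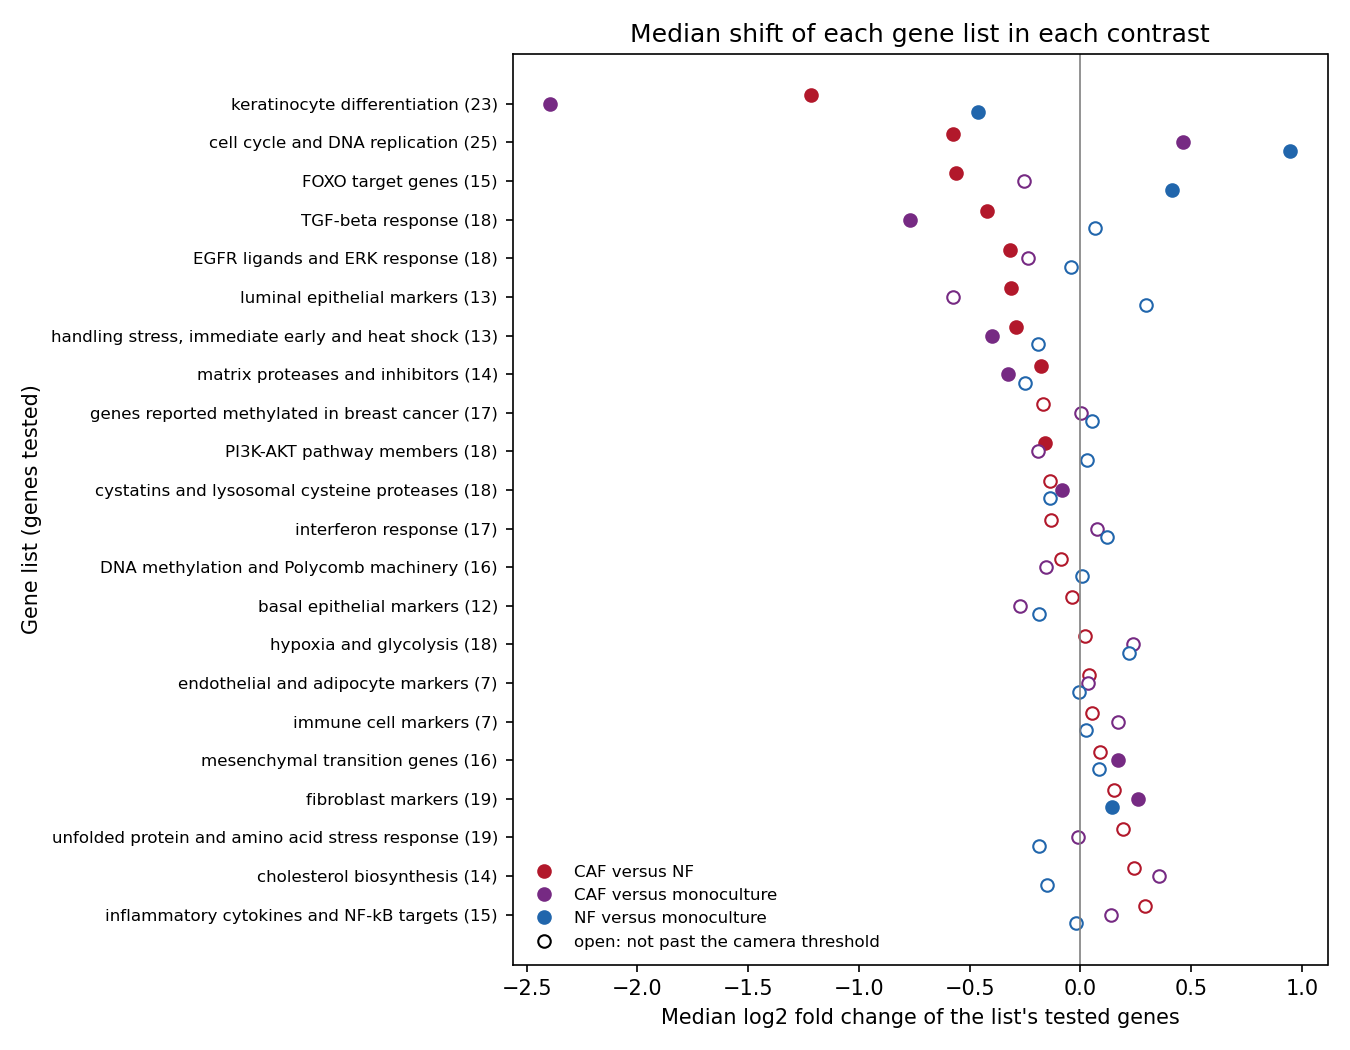
Median log2 fold change (horizontal axis) of the tested genes of each of 22 lists (vertical axis, number tested in brackets) in the 3 contrasts, filled where camera with the preset correlation passed the threshold. Keratinocyte differentiation lies farthest to the left, at −2.40 for CAF versus monoculture and −1.22 for CAF versus NF.

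The 2-fold rule named 40 genes that were lower in each CAF array than in each of the other 3 arrays, and 0 that were higher. Of the 40, 25 were among the genes past the threshold in CAF versus NF, among them LCN2, IVL, SCEL and ALDH1A3. KRT4, KRT13, SPRR3, PSCA, S100P and RARRES1 met the rule without passing the test, and CST6 did not meet it because its monoculture value was within 2-fold of CAF 1. With a 3-fold rule 20 genes were lower, with a 1.5-fold rule 101, and without the monoculture array 73.

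Compared with the monoculture array, MCF10A cells after CAF coculture had less of the transcripts of the chemokine CXCL14, which fell 30.5-fold in its brightest probe set, and of the fatty acid-binding protein FABP4, which fell 26.5-fold. The transcription factors EGR3, ID2 and SOX9 fell 18.6-fold, 13.4-fold and 9.25-fold. In the other direction KRT14, a basal keratin, rose 37.6-fold, from 6.31 to 11.542 ± 0.687 (SD, n = 3). FN1, the matrix protein fibronectin, rose 6.53-fold, and TSC22D3, a glucocorticoid-induced gene, rose 6.05-fold. A rise of FN1 in the epithelial cells cannot be told apart from RNA of fibroblasts that passed the sort. Beside these changes, the fibroblast genes COL3A1, COL6A3, COL1A2 and POSTN lay 3.49, 3.52, 2.74 and 3.10 log2 units above the monoculture array, none past the test (limma adjusted p from 0.126 to 0.283). COL3A1 and COL6A3 read 3.734 and 3.172 in monoculture, and CXCL14 read 4.283 to 4.634 in coculture, all below the level of the filter (4.639), so the sizes of these differences are uncertain. With another probe set the difference of CXCL14 was −1.41 (adjusted p = 0.0415).

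In this contrast 49 of 14390 genes passed in limma, 9 higher and 40 lower with CAF. With the array sets as a term 50 passed if the monoculture array was put with CAF 1 (41 shared with the 49), and 27 if it was put with CAF 3 (26 shared). The count was 29 without CAF 1, 32 without CAF 2, 109 without CAF 3, 188 without NF 1, 190 without NF 2 and 29 with the filter at the 70th percentile. The log2 fold change was −4.93 for CXCL14 (SE 0.189, adjusted p = 0.00567), −4.73 for FABP4 (adjusted p = 0.0136) and −4.22 for EGR3 (adjusted p = 0.0162). The log2 fold changes of AZGP1, TMPRSS11E and DNAJC6 were −4.14, −3.55 and −3.32, with adjusted p of 0.0136, 0.0124 and 0.0284. Their means with CAF, 4.207, 3.861 and 3.899, and the monoculture value of ZBED6, 4.044, also lay below the level of the filter, so these sizes are uncertain too. Rises were 5.23 for KRT14 (SE 0.572, adjusted p = 0.0429), 3.44 for IFITM3, whose probe set can match several transcripts, 2.68 for SAMSN1 and 1.99 for ZBED6. The call of KRT14 ended without CAF 2, with equal array medians and with the filter at the 70th percentile. THRAP3 and CDC27 rose by 1.78 and 1.37; THRAP3 lost its call with the mean of its probe sets (0.29, adjusted p = 0.374), without CAF 1 (adjusted p = 0.0528) and with the monoculture array put with CAF 3 (adjusted p = 0.0761), and CDC27 in either set and in sign with another probe set (−0.17).

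Keratinocyte differentiation genes fell by a median of −2.40 over 23 members relative to monoculture (camera adjusted p = 5.57e-15; adjusted p = 0.295 with an estimated correlation). IVL passed, 22 did not, and 16 were lower adjusted over the list alone. The kallikreins KLK5 and KLK10 differed by −3.14 and −3.06 and KRTDAP by −2.94, with limma adjusted p of 0.0778, 0.172 and 0.079. TGF-beta response genes fell by a median of −0.77 over 18 members (camera adjusted p = 0.00171; adjusted p = 0.295 with an estimated correlation). Here ID2 and ID1, inhibitors of helix-loop-helix factors, and IGFBP3 passed as lower, with IGFBP3 down 9.17-fold (limma adjusted p = 0.0446). The call of ID1 ended with the array sets as a term and the monoculture array put with CAF 3 (adjusted p = 0.0514), without CAF 1 (0.0528) and without an intensity trend (0.0501). That of IGFBP3 ended after quantile normalization (0.0519), with the filter at the 70th percentile (0.0522) and with a robust prior (0.0514). Adjusted over the list alone, 9 were lower and 1 higher.

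Fibroblast markers rose as a group, by a median of 0.26 over 19 members (camera adjusted p = 0.00159, and 0.295 with an estimated correlation). Over the settings tried that median ran from 0.17 to 1.14. None passed singly, and adjusted over the list alone 6 were higher and 1 lower. Mesenchymal transition genes rose by a median of 0.17 over 16 members (camera adjusted p = 0.0223; adjusted p = 0.295 with an estimated correlation), with FN1 past the test and VIM at 2.54 (limma adjusted p = 0.0798). Adjusted over the list alone 3 of them were higher and 1 lower. Both calls ended when probe sets that can match several transcripts were left out (adjusted p = 0.273 and 0.123), as did those of TGF-beta response and matrix proteases (0.125 and 0.128) and of cell cycle genes (0.315). The medians were then −0.18 for TGF-beta response, −0.30 for matrix proteases and 0.25 for cell cycle genes.

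Cell cycle genes rose by a median of 0.46 over 25 members (camera adjusted p = 0.0275; adjusted p = 0.659 with an estimated correlation), 0 of them singly in either adjustment, and the call ended without CAF 1 (adjusted p = 0.0873) and after quantile normalization (adjusted p = 0.0778). Cystatins and lysosomal cysteine proteases fell by a median of −0.08 over 18 members (camera adjusted p = 0.0275; adjusted p = 0.295 with an estimated correlation). CTSH, a lysosomal cysteine protease, fell 3.63-fold (limma adjusted p = 0.0136), but did not pass with the array sets as a term and the monoculture array put with CAF 3 (adjusted p = 0.0698). In this list 4 were lower adjusted over the list alone, and the list's call ended without CAF 2 (adjusted p = 0.0872). Matrix proteases and inhibitors fell by a median of −0.33 (camera adjusted p = 0.00212; adjusted p = 0.295 with an estimated correlation), with PLAU at −1.63 and 3 lower adjusted over the list alone. Handling stress genes fell by a median of −0.40, negative in 13 of 13 members (camera adjusted p = 3.9e-05; adjusted p = 0.491 with an estimated correlation), with 4 lower adjusted over the list alone. Of the luminal markers, whose median was −0.58 (camera adjusted p = 0.0631), the tight junction gene CLDN4 fell 3.37-fold (limma adjusted p = 0.0197). Its call ended with the monoculture array put with CAF 3 (adjusted p = 0.0729), after quantile normalization (0.0519), with the mean of its probe sets (−0.91, 0.0873), and without CAF 1 (0.0528) or CAF 2 (0.0549). The median and the mean had opposite signs for basal markers, at −0.27 and 0.34, where KRT14 alone passed. Of the 14 lists that did not pass in the planned fit, with camera adjusted p from 0.0631 to 0.989, the cytokine list held LCN2, which fell 6.27-fold, and the endothelial and adipocyte list FABP4. With the array sets as a term and the monoculture array in either set 3 of the 14 passed camera, luminal markers and EGFR ligands and ERK response as lower and hypoxia and glycolysis as higher (adjusted p up to 0.0149, 0.0474 and 0.0462). With an estimated correlation in the planned fit their camera adjusted p was 0.295, 0.295 and 0.659.

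**Figure D3:**
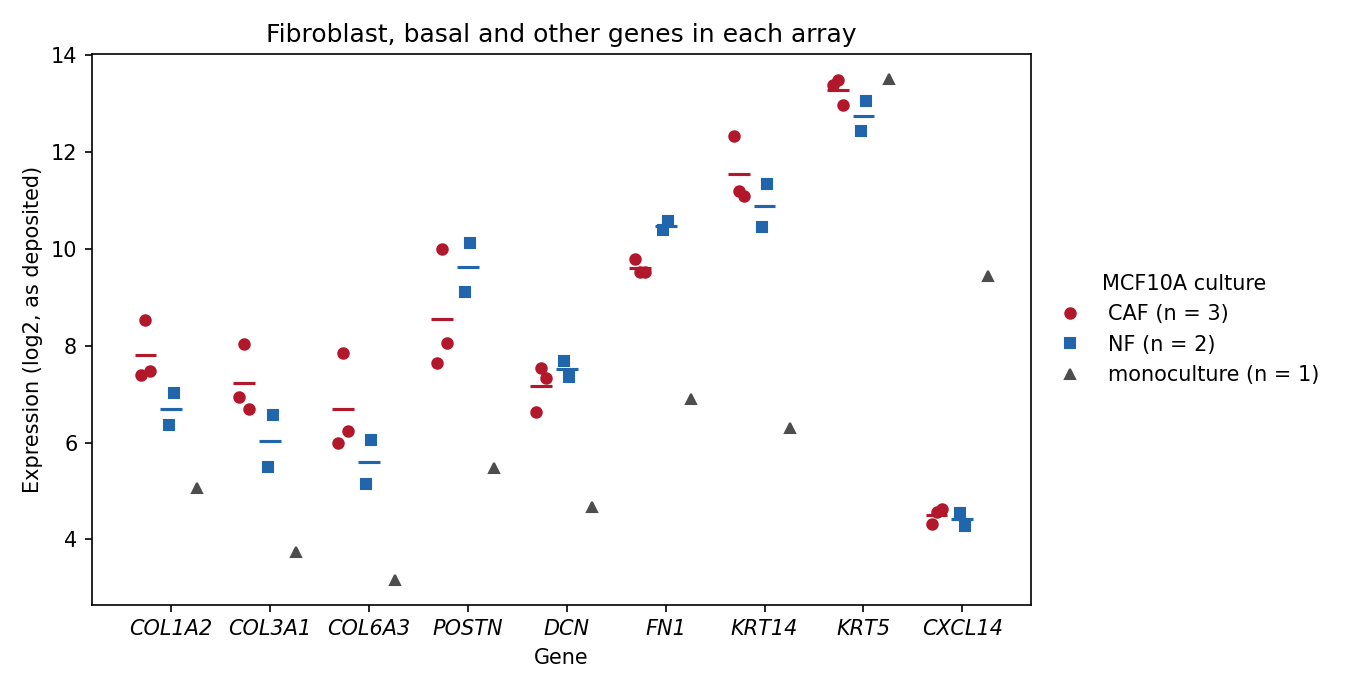
Log2 expression (vertical axis) of 9 genes in each array, with CAF arrays as circles (n = 3), NF arrays as squares (n = 2), the monoculture array as a triangle and group means as short lines. COL1A2, COL3A1, COL6A3, POSTN, DCN, FN1 and KRT14 are lowest in the monoculture array and CXCL14 is highest there, at 9.434 against 4.283 to 4.634 in the 5 cocultured arrays.

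Cells after NF coculture differed from the monoculture array as well. Both coculture contrasts use the same single array, so a gene called in both is not a second, independent result. FABP4 fell 48.4-fold, CXCL14 fell 32.5-fold and ID2 fell 9.51-fold, and the calcium sensor gene VSNL1 fell 8.97-fold. FN1 rose 11.9-fold, from 6.906 to 10.483 ± 0.133 (SD, n = 2), and TSC22D3 rose 6.50-fold. The glycosyltransferase gene GCNT1 and HOPX, an atypical homeodomain protein, rose 4.87-fold and 3.73-fold. KRT14 read 10.898 ± 0.636 (SD, n = 2) with NF against 6.31, a difference of 4.59 that did not pass (limma adjusted p = 0.088). Beside these changes, POSTN and DCN lay 4.16 and 2.85 log2 units above the monoculture array (adjusted p = 0.178 and 0.088).

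Here 14 of 14390 genes passed in limma, 8 higher and 6 lower with NF. The split was 6 higher and 7 lower after quantile normalization, and 8 higher and 9 lower with equal array medians. With the array sets as a term 14 genes passed, 5 higher and 9 lower, and 9 were shared. The count was 3 without CAF 1, 1 without CAF 2, 104 without CAF 3, 45 without NF 1, 157 without NF 2 and 3 when probe sets that can match several transcripts were left out. The log2 fold change was −5.60 for FABP4 (SE 0.367, adjusted p = 0.0251), −5.02 for CXCL14 (adjusted p = 0.00714) and 3.58 for FN1 (SE 0.18, adjusted p = 0.0133). TMPRSS11E and TCN1 had log2 fold changes of −2.39 and −1.91, and SAMSN1, ZBED6, THRAP3 and SCNN1A rose by 2.73, 2.19, 2.06 and 1.18. With the array sets as a term, TCN1, GCNT1, THRAP3, HOPX and SCNN1A did not pass (adjusted p from 0.0552 to 0.108). With the mean of a gene's probe sets 7 of the 14 calls ended: HOPX, THRAP3 and SCNN1A differed by 0.61, 0.68 and 0.44 (adjusted p = 0.131, 0.125 and 0.371), and VSNL1, SAMSN1, TSC22D3 and ZBED6 did not pass either (adjusted p from 0.0718 to 0.078). CD36 and RHOBTB3, at −3.84 and −3.76, filled the rule without passing (adjusted p = 0.0868 for each). With another probe set CXCL14 differed by −1.22 between NF and monoculture and did not pass (adjusted p = 0.102).

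Among the lists, cell cycle and DNA replication genes rose with NF by a median of 0.95 over 25 members (camera adjusted p = 0.000695; adjusted p = 0.735 with an estimated correlation). None passed singly, 1 was higher adjusted over the list alone, and TOP2A and CDC20 differed by 2.94 and 2.76. FOXO target genes rose by a median of 0.41 over 15 members (camera adjusted p = 0.0382; adjusted p = 0.735 with an estimated correlation), with IRS2 at 1.86; adjusted over the list alone 4 were higher and 2 lower. That call ended after quantile normalization (adjusted p = 0.0717), without CAF 2 (0.0619) and without NF 1 (0.0866). Fibroblast markers rose by a median of 0.14 over 19 members (camera adjusted p = 0.0382, and 0.735 with an estimated correlation), 4 of them higher adjusted over the list alone. The call ended with the mean of a gene's probe sets (camera adjusted p = 0.0732), and over the settings tried the median ran from 0.11 to 1.26. Keratinocyte differentiation genes fell by a median of −0.46 over 23 members (camera adjusted p = 0.00904; adjusted p = 0.735 with an estimated correlation). None passed singly, adjusted over the list alone 5 were lower and 1 higher, and KRTDAP and TGM1 differed by −2.57 and 1.97. The call ended without NF 2 (adjusted p = 0.112). Leaving out probe sets that can match several transcripts ended each of these 4 calls (adjusted p from 0.0882 to 0.473). The other 18 lists did not pass, with camera adjusted p from 0.233 to 0.973.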

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

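The tests of the array effect, of the diluting RNA, of the carried-over RNA, of the linear relation and of the splits by the 2-fold rule were chosen after the values they measure had been seen; the splits by limma were set down before.

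Among the 14 genes named in CAF versus NF that passed the threshold, 10 had every CAF array below the monoculture array and both NF arrays above it. None of the 10 passed in NF versus monoculture, and in CAF versus monoculture only LCN2 and ALDH1A3 did (limma adjusted p = 0.0124 and 0.0475), ALDH1A3 not with the array sets as a term (0.0546 or 0.102). These genes had been chosen by their log2 fold change of CAF against NF, so it does not test movement away from the monoculture array; it was −3.39 for SCEL, −2.88 for COXFA4L3, −2.87 for LCN2, −2.71 for ALDH1A3, −2.40 for CST6, −2.21 for IKZF2, −2.21 for ADGRF1, −2.20 for KLK6, −1.82 for INPP4B and −1.56 for DUSP5. CST6 lay 1.04 log2 units below the monoculture array with CAF and 1.36 above it with NF. On 1 side the distance could be small: LCN2 lay 0.22 above with NF (limma adjusted p = 0.588), and INPP4B differed by −0.26 with CAF (adjusted p = 0.714). The monoculture is 1 array.

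A signal outside the main measurement came from the control probe sets. The 18S ribosomal RNA 3′ probe set was highest in CAF 1, at 12.008, which is 3.86 log2 units above the monoculture array at 8.149, while CAF 2 read 8.291. The hybridization spike probe sets averaged 9.913 with CAF and 9.525 with NF, a difference of 0.39 log2 units, and in 6 of 9 of them every CAF array lay above both NF arrays. The ACTB 3′ probe set minus the 5′ one, a measure of RNA quality, was 0.075 to 0.181 in the CAF arrays. It was −0.068 and 0.017 in the NF arrays and 0.257 in monoculture. The same measure for GAPDH overlapped between CAF and NF.

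The first pattern weighed is the one-sided change, 50 genes lower and 0 higher with CAF. It was less one-sided in other settings, with 14 genes higher and 122 lower without CAF 3 and 14 higher and 117 lower without NF 2. The array effect that was apparently removed before deposit left less spread. This is unlikely to account for the calls as a whole, since 44 genes were lower and 0 higher with the array sets as a term. That term leaves the fold changes and their signs as they are, so it tests the spread and not the one-sidedness. Dilution by fibroblast RNA that gave the median of the called genes, −1.64, would lower all epithelial transcripts by about as much. Against dilution of that size, the 12 basal epithelial markers had a median of −0.0393 with an SD of 0.471 over members. The called genes were chosen for large falls, and a smaller dilution that adds to them was not tested. Luminal epithelial markers had a median of −0.32. Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 36 genes in limma and the highest other 0, and 40 genes by the 2-fold rule against at most 1; as many genes came from 1 of the 10 splits, the real one, in both counts, and 10 splits are too few for a share under 0.05. The comparison is limited further by the effect that was apparently removed, since the split of CAF 1, CAF 2 and NF 1 from the rest would have been driven towards 0 with the real groups kept. A difference between the fibroblast groups stays open as the explanation named by the design, as does the small number of sources per group. A technical difference stays open too, because the hybridization spikes also set the CAF arrays apart. Their mean lay between 9.779 and 10.046 in the CAF arrays and between 9.391 and 9.659 in the NF and monoculture arrays. No test here separates it from the fibroblast group.

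The second pattern is the higher level of fibroblast genes in cocultured cells. Of 22 fibroblast genes on the array, 6 (COL1A2, COL3A1, COL6A1, COL6A3, DCN and POSTN) lay at least 1 log2 unit higher in each of the 5 cocultured arrays than in the monoculture array, and 12 were not higher in all 5. MMP2 and THY1, at 5.947 and 5.611 in monoculture, read 5.432 to 6.005 and 5.453 to 5.908 in coculture. RNA carried over from fibroblasts that passed the sort and expression by the epithelial cells themselves cannot be told apart, because the series holds no array of fibroblasts alone and 1 array without them. The same limit holds for FN1, which was also lowest in the monoculture array, and for the mesenchymal transition genes that were higher in coculture.

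The third pattern is the exact linear relation between the 5 cocultured arrays. A candidate explanation is that an effect of 2 sets of arrays was subtracted with the groups kept: 1 of the 14 splits into 2 sets left a coefficient of 0 at every probe set, and the next left up to 1.76. The rank of 4 among the 5 arrays would also arise if 1 array had been computed from the others, and the table alone does not decide this. No biological explanation was tested.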

How the results depend on the processing

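The fits with the array sets as a term were chosen after seeing the data; all other settings were planned, and offsets before logs were not run. Of the settings tried for lists called in the report, 322 kept the call and direction and 53 lost the call. For named genes 594 kept and 120 lost it, and 1 changed sign. That was CDC27 in CAF versus monoculture, at −0.17 without probe sets that can match several transcripts. Genes not tested in a setting count as neither kept nor lost. Without those probe sets, 11 of 21 called named genes were tested for CAF versus monoculture and 9 of 14 for NF versus monoculture. The gene count of CAF versus NF was 22 after quantile normalization and 91 with the filter at the 70th percentile, where fewer genes are tested; that of CAF versus monoculture was 29 with that filter, 91 per probe set and 27 with the array sets as a term and the monoculture array put with CAF 3; that of NF versus monoculture was 3 without probe sets that can match several transcripts and 33 per probe set. CST6 in CAF versus NF stayed below 0 in all 18 settings and past the threshold in 14, with adjusted p from 0.00523 to 0.479; it differed by −1.95 (adjusted p = 0.143) with NF and monoculture as 1 group and by −0.26 in its dimmer probe set. The AKT1 transcript in CAF versus NF passed in 0 of 16 settings. The lists passing in all contrasts numbered 21, against 0 with an estimated correlation and 11 by fry. In CAF versus NF, fry kept luminal markers (fry adjusted p = 4.4e-05), and 4 of 9 lists lost their call. These were keratinocyte differentiation (fry adjusted p = 0.0534), cell cycle (0.276), PI3K-AKT pathway members (0.18) and handling stress (0.295). The 2-fold rule gave 101 lower and 1 higher genes at 1.5-fold, 20 lower at 3-fold, and 73 lower and 1 higher against the NF arrays only. With 1 array left out, the count ranged from 0 to 136 for CAF versus NF, from 29 to 190 for CAF versus monoculture and from 1 to 157 for NF versus monoculture, CST6 from −2.57 to −2.27, and the 2-fold rule from 43 to 73 lower and from 0 to 2 higher; a group left with 1 array was assumed to vary like the others. Beyond the filter, the cause was not tested. No pairing by replicate number was made, because these only name the arrays; the array sets served as blocks. Probe sets near background, such as the dimmer one of CST6, limit what a fold change can show.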

Other observations

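The list of NRF2 targets and its tests were chosen after AKR1B10, SLC7A11 and ABCC2 had been seen, and the position of the monoculture array was examined after the calls.

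For 43 of the 50 genes lower with CAF than with NF, the monoculture array lay above every CAF array, and for 13 it also lay above both NF arrays. This was 86% of the genes, against a median of 30% and at most 56% in 10000 draws of random genes matched on mean level; the called genes were chosen for low CAF values, which raises the share by itself. In the median gene the monoculture array lay 0.699 of the way from the CAF mean to the NF mean. IVL, at 8.671 in monoculture, was near its NF mean of 8.516, while AZGP1, at 8.349, was above its NF mean of 6.797.

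AKR1B10, SLC7A11 and ABCC2, each known as a target of the oxidative stress factor NRF2, were higher in every CAF array than in both NF arrays without passing the test. The hypothesis that NRF2 activity may be higher with CAF was tested on 18 other NRF2 targets. Their median log2 fold change was 0.25, with 13 positive, 5 negative and 0 past the threshold, and it lay at the 99.92 percentile of 10000 random lists matched on mean level. The median was 0.15 without CAF 1 and between 0.20 and 0.34 without 1 of the other cocultured arrays; NQO1 and PIR read 9.648 and 9.415 in CAF 1 but 8.08 and 7.378 in CAF 2, below both NF arrays. Random lists ignore that genes of a pathway vary together. By camera p was 0.0373 with the preset correlation. It was 0.433 with an estimated correlation, where fewer degrees of freedom also raise p, so these arrays do not decide the hypothesis. HMOX1 and GCLM, which NRF2 also induces, differed by −0.52 and −0.50 with CAF (limma adjusted p = 0.133 and 0.187). The comparison is with NF coculture, so lower levels with NF would give the same median. The monoculture array lay above every CAF array for some members, such as TXNRD1 (10.641). It lay below every CAF array for others, such as ME1 (8.023).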
